A study of Mus musculus with 6 samples.

How the data were processed

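The data were RPKM values (reads per kilobase of gene model, scaled to the alignments of each library) for 12331 gene rows in 6 libraries of the mouse embryonic stem cell line E14tg2a, 3 made by sonication and 3 by tagmentation. Per the labels' protocols, total RNA was prepared from the cells, and 10 pg of it was reverse transcribed with a tagged oligo(dT) primer. A poly(A) tail was added to the first strand, and the double-stranded product was amplified with 20 PCR cycles. Per the labels, the sonication libraries were fragmented with an acoustic sonicator and made with an mRNA-seq kit, and the tagmentation libraries were made from 100 ng of cDNA at 55 °C for 5 min followed by 13 PCR cycles. These steps bear on the values: at 10 pg many transcripts are present in few copies and can be lost before amplification. PCR reads without molecular identifiers are not independent molecules, so any interval or limit covers counting error only.

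The RPKM values were made by the authors before they were deposited, per the file headers, which also give the number of alignments of each library. The submitters' processing notes name the genome build mm9 and the tools CASAVA 1.7.0 and Partek without saying which did what; the aligner, the gene annotation and the treatment of reads with several matches are not given in the sources used here. Each library had its own column, and none was pooled. The deposited RPKM values fit the alignment totals in the headers: of 9531 genes with at least 4 values above 0, 78.4% gave whole reads in all of them (within 0.002 reads, with a gene length found from the steps), against 2.94% when the totals were moved by 1 library. In simulated data, 99.1% of 458 genes were recovered. For the remaining genes no such length was found. The tolerance also grew by 1e-05 of the reads, so genes of very many reads, such as Rpl8, could give no length. The simulated genes had far fewer reads and do not test this. The 60 to 94 values per library above 0 but under 1e-04 RPKM were not multiples of a whole read. At the median transcript length of 2569 bases, 1 read was worth 0.0112 to 0.0206 RPKM, so that 1 RPKM stood well above the counting limit in each library.

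Libraries were assigned to groups and numbers by their labels. A chi-square on the recovered reads per degree of freedom was 64.1 to 111 for libraries of the same number and 330 to 1057 for other pairs, so no library was a repeat of another. Values were tested as log2(RPKM + 1), with genes kept at 1 RPKM or more in at least 3 of the 6 libraries, which left 6327. Fold changes on this scale understate the change of low genes. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and with the method as the only term. Because both groups carry the numbers 1 to 3, the fit with the number as a block was set as an alternative before the data were examined, together with the tests, the gene lists and the other alternatives. The labels say that all cDNA came from E14tg2a RNA and do not say that libraries of the same number share a cDNA. The data were checked for this: deviations from the group means correlated by 0.952, 0.969 and 0.934 between libraries of the same number. Between methods at different numbers they correlated by -0.175 or less. Deviations sum to 0 within a method, which by construction pushes the latter below 0. Without taking off the means, correlations between methods were 0.958 to 0.977 for the same number and 0.482 to 0.705 for different numbers. The numbers were therefore taken as pairs, and blocked values are given beside results that they change. Tested on simulated data with the spread of these 6327 genes and 200 changed ones, limma without the block recovered 0% of 2-fold and 0% of 4-fold changes. With the block it recovered 2% and 65%, with 0 false calls in both fits. A list of 30 genes shifted by -0.50 was found with and without the block. The simulated noise was independent between genes and had no link to GC content. These shares, the false calls and the list result therefore need not hold for the real libraries.

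The gene lists covered the pluripotency network, LIF and BMP signalling, formative and primed epiblast, extraembryonic endoderm, primitive streak and mesoderm, neuroectoderm, trophoblast, fibroblast and 2-cell-like state markers. They further covered cytosolic ribosomal proteins, the nuclear-encoded respiratory chain, glycolysis, DNA replication and mitosis, proteasome subunits, chromatin regulators, imprinted genes, heat shock and stress, replication-dependent histones and mitochondrially encoded genes, 19 lists in all. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. List members under other symbols, such as Mll1 for Kmt2a, were matched through a name table. Genes were named by a rule. It took those called with a mean of at least 10 RPKM and no overlap between groups, or up to 5 per direction by unadjusted p where too few passed; 10 fixed stem cell and reference genes; and per list up to 2 called members per direction or the 2 of highest level. The same rule was applied to the blocked calls after the data were seen, with pairs in the same direction in place of groups without overlap. Genes named outside the rule were chosen after their values were seen: Lin28a, Socs3, Id3, T, Cldn6, Fkbp1b, Hscb, Lysmd2, Ptpla, Col1a1, Col1a2 and Col3a1.

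Transcript length and GC content came from GENCODE M21, a later build than mm9, used by gene name only and with no coordinates; 11103 names matched directly, 1053 through synonyms and 175 not at all, and 99.0% of tested genes had a value. The 21 rows named by digits alone were kept under those names and none is reported. Some results for single genes that the rule names are not reported here. Differences between groups in single values were tested by exact permutation over 10 splits, and by an exact sign-flip test over 3 pairs. Alternatives were other pseudocounts (0.1 and 5), no filter or a filter at a mean of 10 RPKM, median-ratio and quantile scaling, eBayes without a trend, leaving out each library or pair, and, added after the data were seen, the same changes within the block and corrections for GC content and length. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.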

Results

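Gene expression was measured in 6 RNA-seq libraries from E14tg2a, an established mouse embryonic stem cell line. The cells were kept in medium with LIF, the cytokine that holds them undifferentiated. The libraries started from 10 pg of total RNA, about the content of a single cell. It was turned into cDNA by oligo(dT) priming and amplified by PCR. In 3 libraries the cDNA was fragmented by sonication and ligated to adaptors, and in the other 3 it was cut and tagged in one reaction by hyperactive Tn5 transposase (tagmentation). Both groups carried the replicate numbers 1 to 3. The sonication libraries had 30296557, 22002643 and 18852822 alignments, in that order. The tagmentation libraries had 21007424, 34612028 and 34681566. The replicates were technical, so the p-values measure only the spread between these libraries and not between cultures. The series asked how the 2 ways of making a library compare for cDNA of single-cell amount.

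Transcripts of the stem cell network were found in libraries of both methods. Pou5f1, the transcription factor also called Oct4, had 175 ± 80.0 RPKM after sonication and 166 ± 81.7 RPKM after tagmentation (SD, n = 3). Dppa5a, a marker of pluripotent cells, had 997 ± 665 RPKM and 1098 ± 485 RPKM. Zfp42 (Rex1), another marker of the undifferentiated state, had 212 ± 46.8 RPKM and 350 ± 126 RPKM. Of 27 tested members of the pluripotency network, none differed between methods in limma's test (Benjamini-Hochberg adjusted), over all genes or adjusted over the list alone. With the replicate number as a block 1 did, Fbxo15, which was lower (adjusted p 0.00152). Its decrease lay in numbers 2 and 3, while number 1 had 98.9 RPKM after sonication and 95.9 RPKM after tagmentation. The median log2 fold change of the list, tagmentation over sonication on the log2(RPKM + 1) scale used throughout, was 0.17. Actb, the cytoskeletal actin, and Gapdh, a glycolytic enzyme, gave log2 fold changes of 0.16 (SE 0.45) and -0.44 (SE 0.42), also not called. The fit without the block recovered 0% of simulated 4-fold changes, so its lack of calls cannot show that the methods gave equal levels.

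**Figure D1:**
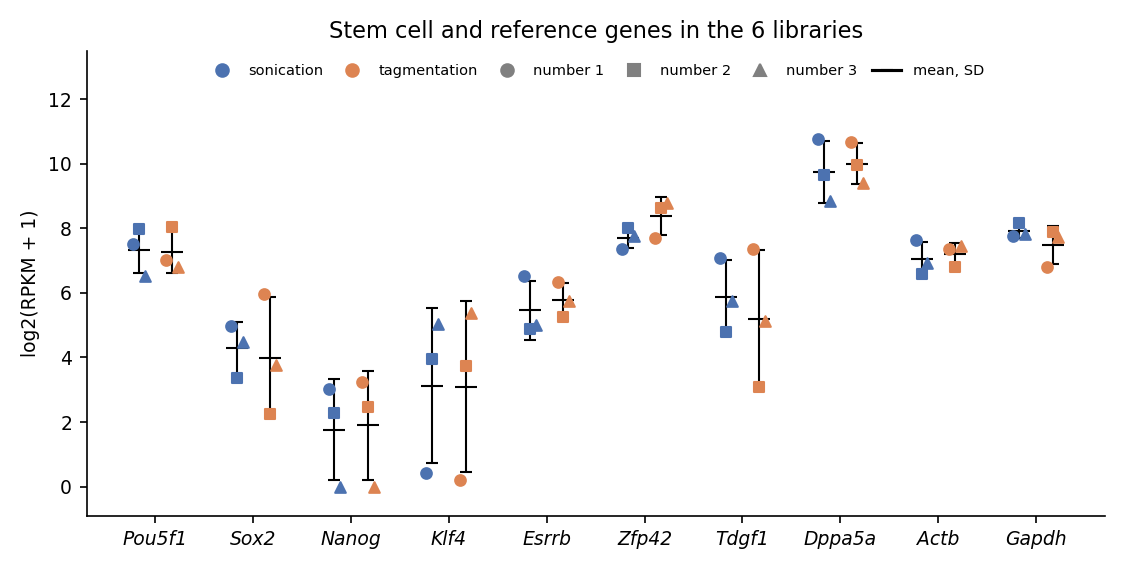
Expression of 8 stem cell genes and of Actb and Gapdh as log2(RPKM + 1), 1 point per library, with sonication and tagmentation side by side, a symbol for each replicate number, and black lines for the mean and SD over 3 libraries. Klf4 stood at 0.336 and 0.141 RPKM in number 1 and at 31.6 and 40.4 RPKM in number 3.

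Single genes that stood apart between methods in all libraries were led by Ptma, which encodes the abundant nuclear protein prothymosin alpha, with 557 ± 77.8 RPKM after sonication and 1320 ± 103 RPKM after tagmentation (SD, n = 3). Fkbp3, a peptidyl-prolyl isomerase, had 249 ± 81.4 RPKM against 566 ± 13.9 RPKM. Dstn, the actin-depolymerizing protein destrin, had 328 ± 107 RPKM against 622 ± 80.1 RPKM. In the other direction stood Arhgdia, with 181, 192 and 152 RPKM in sonication libraries 1 to 3 against 71.1, 131 and 110 RPKM. Pgls, an enzyme of the pentose phosphate pathway, had 60.5 ± 4.89 RPKM against 31.0 ± 6.80 RPKM. None of these passed the test. Limma called 0 of 6327 genes at an adjusted p under 0.05, with 18 at an unadjusted p under 0.05. Ptma had an unadjusted p of 0.00167 and an adjusted p of 1.00. The 3 libraries of each method did not overlap in 152 genes, 2.40% of those tested. Chance gives 10% if all 6 libraries are exchangeable, which these are not, since their numbers pair them. The other genes named by the same rule and not called were Gm10012, Gm12166, Gm13611, Gm11517 and Tmem160.

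With the replicate number as a block, which the libraries' own correlations called for, limma called 208 genes, 100 higher and 108 lower after tagmentation. Ptma (log2 fold change 1.25, SE 0.30, adjusted p 0.00594), Fkbp3 (1.24, SE 0.30, adjusted p 0.00711), Dstn (0.97, SE 0.30, adjusted p 0.0466) and Pgls (-0.97, SE 0.30, adjusted p 0.0441) were among them, each in the same direction in 3 of 3 pairs. Arhgdia was not called (-0.78, adjusted p 0.132). In this fit limma took the spread almost wholly from genes of like level (210 prior degrees of freedom). The SEs and p-values with the block therefore say little of a gene's own spread over the 3 pairs. Rap1a, a small GTPase of cell adhesion, was higher after tagmentation by 1.44 (SE 0.30, adjusted p 0.00079). Sec23a, a coat protein of vesicles leaving the endoplasmic reticulum, was higher by 1.39 (SE 0.29, adjusted p 0.00115). Suz12, a core subunit of Polycomb repressive complex 2, was higher by 1.25 (SE 0.29, adjusted p 0.00427). Lower were Fcf1, a factor of small ribosomal subunit assembly, with -1.67 (SE 0.30, adjusted p 3.7e-05). Fbxo15, an F-box gene active in stem cells, was lower with -1.37 (SE 0.30, adjusted p 0.00152). Both decreases came mostly from numbers 2 and 3, where these genes stood low. In number 1 Fbxo15 had 98.9 RPKM after sonication and 95.9 RPKM after tagmentation, and Fcf1 had 103 and 86.9 RPKM. Fbxo15 had 7.31 and 0.965 RPKM in number 2, and 9.60 and 1.65 RPKM in number 3. Fcf1 had 13.1 and 1.94 RPKM in number 2, and 18.1 and 2.38 RPKM in number 3. The most extreme called values belonged to the predicted genes Gm12166 (2.72, SE 0.30) and Gm9786 (-2.81, SE 0.30). Gm10012 (1.37, SE 0.30) and Gm11517 (-1.01, SE 0.30) were also called, and Gm13611 and Tmem160 were not. Predicted genes can share reads with near-identical copies elsewhere, so these are uncertain. Of the 208 genes, 110 had a mean of at least 10 RPKM and the same direction in 3 pairs, 80 higher and 30 lower. Their largest increases also included 2410127L17Rik, Usp38, Ccdc90b and Mzt1, and their largest decreases 2810432D09Rik and several histone genes.

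The blocked count moved with the processing: it was 104 with median-ratio scaling (70 higher and 34 lower), 476 with quantile normalization, 8 with a pseudocount of 0.1, 0 with no filter and 5 after a correction for GC content. With that correction the degrees of freedom of the test fell from 212 to 9.62. Setting the t values (log2 fold change over SE) of one fit against the degrees of freedom of the other gave mixed counts. They were 310 genes for corrected t values at 212, and 7 for uncorrected ones at 9.62. Mixed counts belong to neither fit, because each fit estimates its SEs and its degrees of freedom together. The blocked count was also 1051 without replicate 1 (662 higher and 389 lower), 10 without replicate 2 and 19 without replicate 3.

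Replication-dependent histone genes, whose transcripts are made during DNA synthesis, were called lower after tagmentation as a list. Their 31 tested members had a median log2 fold change of -0.76, with 27 values below 0 (camera with a preset correlation of 0.01, adjusted p 2.51e-12). With an estimated correlation the list was not called (adjusted p 0.648, or 0.158 with the block). No member passed on its own without the block, while 14 were called lower with it, all of them H2A genes, and 17 adjusted over the list alone. Hist1h2ao had 25.4, 69.6 and 148 RPKM in sonication libraries 1 to 3 and 8.33, 36.8 and 78.4 RPKM in tagmentation libraries 1 to 3. Hist1h2ah had 7.51, 25.5 and 48.2 RPKM against 2.09, 8.73 and 18.1 RPKM, and Hist2h2aa2 had the lowest called log2 fold change of the family, -1.66 (SE 0.29). The 16 tested H2A genes, set apart after their values were seen, had a median of -1.21, and the 15 other histone genes a median of -0.30 with none called. The others had means below 10 RPKM, a level at which log2(RPKM + 1) understates changes. H2A genes are near-identical copies whose reads can be split between them, so their 14 calls are not separate measurements. After the GC correction 0 of them were called, at a median of -0.82, and 9 in the mixed count with the degrees of freedom before it. The other histone genes then had a median of -0.12, with 8 of 15 below 0, and the list as a whole a median of -0.49. Without the block the call on the list also ended without sonication replicate 3 (median -0.25, adjusted p 0.885) or without tagmentation replicate 1 (median -0.29, adjusted p 0.219). Its median was -1.34 without tagmentation replicate 3, -1.25 without sonication replicate 1, -0.31 with a pseudocount of 5, -0.29 with no filter and -1.30 with a filter at a mean of 10 RPKM.

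**Figure D2:**
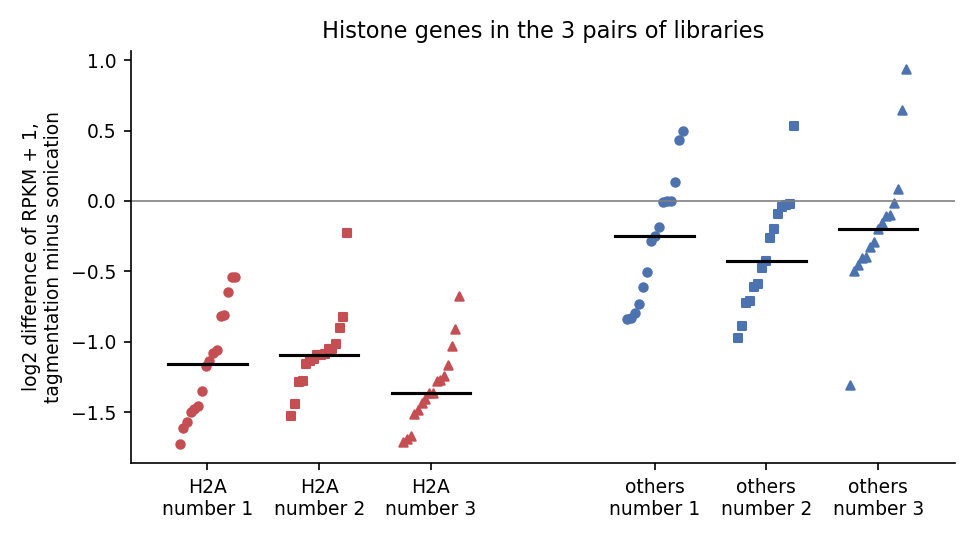
Difference of log2(RPKM + 1) between the tagmentation and the sonication library of the same number, 1 point per histone gene, for the 16 H2A genes and the 15 other histone genes tested, with a black line at each median. The H2A medians are -1.16, -1.09 and -1.37 in numbers 1 to 3, and those of the other histone genes are -0.25, -0.43 and -0.20.

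Ribosomal protein genes and genes of LIF and BMP signalling were the other lists called. The 78 cytosolic ribosomal proteins had a median log2 fold change of -0.17 (camera, adjusted p 2.46e-04, and 0.0241 with the replicate block). With an estimated correlation they were not called (adjusted p 0.648, and 0.956 with the block), nor with the block after a length correction (median -0.048, adjusted p 0.263). Rpl8 had 4789 ± 945 RPKM after sonication and 3641 ± 1403 RPKM after tagmentation (SD, n = 3). Rpl8 was not called in either fit, and Rps27 was called lower with the block (-1.08, SE 0.30). The 11 tested genes of LIF and BMP signalling had a median of 0.48 (adjusted p 0.0229, and 0.0131 with the block) and 1 of them was below 0. With an estimated correlation they were not called (adjusted p 0.648, and 0.956 with the block). Ctnnb1, which encodes beta-catenin, had 147 ± 76.9 RPKM against 222 ± 72.5 RPKM and was not called. With the block the 19 tested chromatin regulators were also called (median 0.35, adjusted p 0.0131, against 0.0783 without it), but not with an estimated correlation (adjusted p 0.956). Suz12 and the deacetylase gene Hdac1 (1.01, SE 0.30, adjusted p 0.0315) were called higher, and Trim28 and Mbd3, the members with the highest level, were not called. With the block the chromatin list also lost its call with a length correction (adjusted p 0.0839), a filter at a mean of 10 RPKM (0.156) and quantile normalization (0.162), and its median was 0.14 to 0.58 over all alternatives. The ribosomal median turned to 0.054 without tagmentation replicate 1 (adjusted p 0.795) and, with the block, to 0.041 without replicate 1 (adjusted p 0.378). The call on ribosomal proteins also ended without sonication replicate 1 (median -0.010, adjusted p 0.103), and that on LIF and BMP signalling without any 1 of sonication replicates 1 and 2 and tagmentation replicates 1 and 3 (adjusted p 0.163 to 0.789). The median of the latter was 0.19 to 0.74 without each library.

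No other gene list was called, with adjusted p from 0.0783 to 0.402 without the block. The median log2 fold changes were 0.21 for 30 genes of DNA replication and mitosis, 0.086 for 74 nuclear-encoded respiratory chain genes and 0.032 for 31 proteasome subunits. They were -0.096 for 14 glycolysis genes, 0.16 for 18 heat shock and stress genes and 0.14 for 9 imprinted genes. Among developmental markers they were 0.39 for 9 formative and primed epiblast genes, 0.025 for 5 primitive streak and mesoderm genes (mean -0.17, test direction down) and -0.59 for 3 extraembryonic endoderm genes. They were -0.20 for 3 neuroectoderm genes, -0.20 for 5 trophoblast genes and -0.20 for 4 fibroblast genes. Each of these medians and that of the pluripotency list turned direction without at least 1 of the libraries. The range was -1.73 to 0.45 for endoderm, -1.04 to 0.30 for mesoderm and -0.030 to 0.61 for pluripotency genes. With the block, 1 member each was called in 4 of these lists and in the pluripotency list. They included Fbxo15 lower in the pluripotency list, Pou3f1 higher (0.98, SE 0.29) among epiblast genes and Lefty1 lower (-0.95, SE 0.30) among mesoderm genes. The Lefty1 value came mostly from number 3, with 4.79 RPKM after sonication and 0.449 RPKM after tagmentation. The others were Atp5j lower (-1.04, SE 0.29) in the respiratory chain and Mest higher (0.96, SE 0.30) among imprinted genes. The 7 listed genes of the 2-cell-like state, such as Zscan4c and Zfp352, were below 1 RPKM in all 6 libraries and none was tested, and mitochondrially encoded genes were not analysed here.

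The level of single genes followed the replicate number far more than the method. Klf4, a transcription factor of naive stem cells, was at 0.336 RPKM in sonication and 0.141 RPKM in tagmentation library 1, at 14.3 and 12.3 RPKM in number 2, and at 31.6 and 40.4 RPKM in number 3. Nanog, another core stem cell factor, had 7.16 and 8.39 RPKM in number 1 and 3.85 and 4.48 RPKM in number 2. It was listed at 0 in both libraries of number 3, where 3 reads would have given 0.0720 and 0.0391 RPKM. Sox2, which partners Pou5f1, was highest in number 1 with 30.7 and 61.6 RPKM and lowest in number 2 with 9.33 and 3.79 RPKM. With method as a term, 5577 of 6327 genes (88.1%) differed between numbers in limma's test at an adjusted p under 0.05, 3704 of them by 4-fold or more. The number took 94.3% of the sum of squares against 2.84% for the method. Among the lists, 23 of 27 pluripotency genes differed between numbers, 16 of them by 4-fold or more, and 29 of 78 ribosomal protein genes, 7 by 4-fold or more. Since each number has 1 library per method, this test takes the difference between methods in a pair as its error.

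Across the tested genes the Pearson correlation of log2(RPKM + 1) was 0.970 on average for the 3 pairs of libraries of the same number and different method (0.958 to 0.977). It averaged 0.611 within sonication (0.549 to 0.723) and 0.541 within tagmentation (0.453 to 0.704), and 0.566 between methods for different numbers. The mean within methods minus the mean between methods was -0.125, with the 3 same-number pairs counted as between methods. Without these pairs the means were near each other, 0.576 within methods and 0.566 between them. An exact permutation test over the 10 splits gave a one-sided p of 0.7 for higher correlation within methods. In 4 of these splits, the real one included, all 3 same-number pairs count as between methods. In the other splits some count as within, which puts those splits higher. The pairing thus kept this p from being low, and the test says nothing about the methods. Genes are not independent replicates, so these values describe the libraries only.

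**Figure D3:**
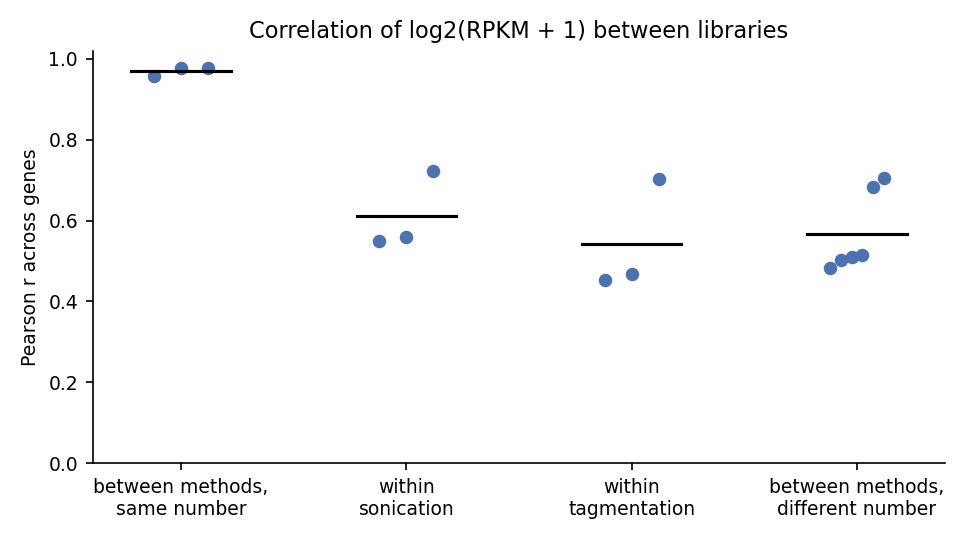
Pearson correlation across 6327 genes of log2(RPKM + 1) for each of the 15 pairs of libraries, grouped by whether the method and the replicate number are shared, with a black line at each mean. Pairs that share the number lie at 0.958 or above, and no other pair is above 0.723.

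Genes of low and middle level varied most between replicates of a method, and abundant genes such as those of ribosomal proteins least. The median SD of log2(RPKM + 1) over 3 libraries was 1.17 after sonication and 1.32 after tagmentation, a ratio of 1.12. In the 3304 genes with a mean of 10 to 100 RPKM it was 1.28 and 1.39. In the 38 genes over 1000 RPKM, among them Rpl8 and Dppa5a, it was 0.28 and 0.55. Of these 38 genes 81.6% were wider after tagmentation, but Dppa5a was not. Their methods differed most in number 1, with median absolute log2 differences of 0.63, 0.21 and 0.22 in numbers 1 to 3. Rpl8 had 2093, 4830 and 3999 RPKM in tagmentation libraries 1 to 3. Over all tested genes, libraries of the same number differed between methods by a median SD of 0.32.

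Fewer genes reached 1 RPKM after tagmentation. The counts were 6807, 6355 and 6077 in sonication libraries 1 to 3 and 6784, 5954 and 5426 in tagmentation libraries 1 to 3, or 6413 ± 368 against 6055 ± 685 (SD, n = 3; exact two-sided permutation p = 0.4, where 0.1 is the smallest possible). Tagmentation had fewer in 3 of 3 pairs (exact sign-flip p = 0.25, the smallest that 3 pairs allow). At 10 RPKM or more the direction turned, with 3488 ± 572 genes after sonication and 3659 ± 367 after tagmentation (exact permutation p = 0.7).

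The 100 most abundant genes, which include Rpl8, took 36.2 ± 3.57% of the summed RPKM after sonication and 32.5 ± 3.70% after tagmentation (SD, n = 3; exact two-sided permutation p = 0.3). The share was lower after tagmentation in 3 of 3 pairs, with differences of -3.96, -2.96 and -4.11 percentage points in numbers 1 to 3.

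Transcript length and base content were compared with the method difference in 6265 tested genes with a reference transcript. The longest class of 3 equal classes minus the shortest had a mean log2(RPKM + 1) difference of -1.92 ± 0.19 after sonication and -1.81 ± 0.34 after tagmentation (SD, n = 3; exact two-sided permutation p = 0.7). For GC content, the class richest in GC minus the poorest gave 0.75 ± 0.76 and 0.49 ± 1.18 (exact two-sided permutation p = 0.7), and the change with method was -0.75, -0.055 and 0.030 in numbers 1 to 3. Across genes, the Spearman correlation of the log2 fold change was 0.117 with length and -0.293 with GC content. In numbers 1 to 3 it was 0.252, 0.0563 and 0.0197 for length, and -0.676, -0.201 and -0.0801 for GC. The 627 genes richest in GC, with a median of 60.2%, had a median log2 difference of -0.61, -0.13 and -0.025 in the 3 pairs. The 627 poorest, with a median of 41.1%, had 0.50, -0.052 and -0.35. The H2A genes had a median GC content of 64.2%. The direction of the GC trend turned without sonication replicate 2 (0.018) and without tagmentation replicate 1 (0.42), and that of the length trend without tagmentation replicate 1 (-0.083).

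**Figure D4:**
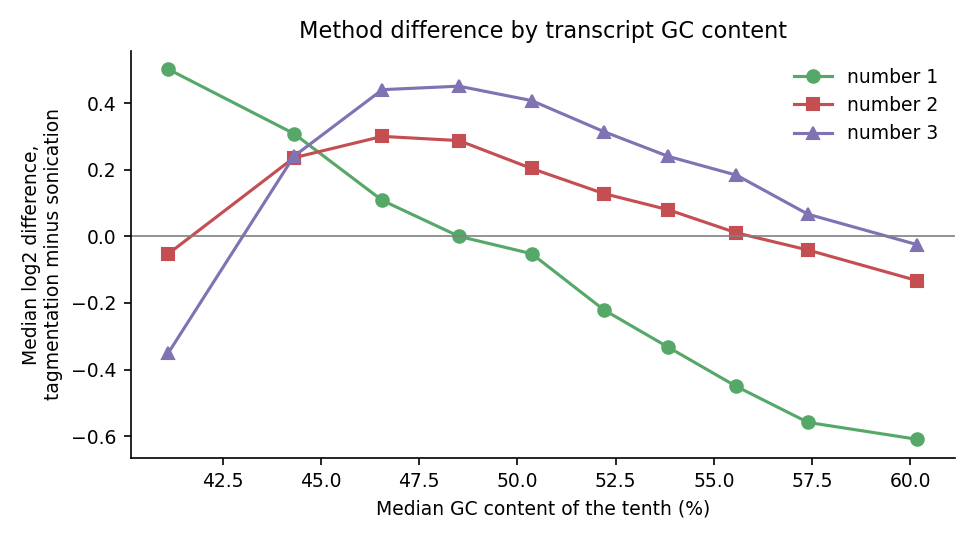
Median difference of log2(RPKM + 1) between the tagmentation and the sonication library of the same number in 10 equal classes of genes by transcript GC content, plotted at the median GC content of each class in percent, with 1 line per replicate number. The class richest in GC lies at -0.61, -0.13 and -0.025 in numbers 1 to 3, while the poorest lies at 0.50, -0.052 and -0.35.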

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

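The alternatives within the replicate block, the corrections for GC content and length, the sign-flip tests of pairs and the separate H2A list were chosen after seeing the data; all others were planned. Without the block, limma called 0 genes under each alternative. The block itself changed this count to 208, raised the called gene lists from 3 to 4 and changed no other call in the report beyond those printed there. For genes differing between methods with the replicate block, the count was 8 with pseudocount 0.1, 0 with no filter and 104 with median-ratio scaling. It was 476 with quantile normalization and 5 with GC correction (310 in the mixed count at the degrees of freedom before it). It was 1051 without replicate 1, 10 without replicate 2 and 19 without replicate 3. It was 145 at 2-fold or more and 168 with pseudocount 5 (118 higher and 50 lower). Of 33 named genes called with the block, 2 were still called with pseudocount 0.1, 2 with GC correction, 0 with no filter, 32 without replicate 1, 2 without replicate 2 and 5 without replicate 3, and none changed sign. Leaving out a number leaves 2 pairs, which lowers the power by construction. The prior degrees of freedom fell from 210 to 7.62 with GC correction, 7.87 with pseudocount 0.1 and 1.81 with no filter. They also fell to 4.18 with quantile normalization and 8.44 without replicate 1, so a fall did not always go with fewer calls. The cause of the higher count without replicate 1 was not tested, nor that of the other changes.

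For the gene lists without the block, 5 were called with median-ratio scaling, 0 with an estimated correlation, 0 with fry, and 0 to 4 without each library in turn; leaving out 1 library of a pair unbalances the numbers, which by construction moves the contrast. For the gene lists with the replicate block, 2 were called with no filter, 2 with transcript length correction, 0 with an estimated correlation and 1, the histones, with fry; without each replicate in turn it was 2 to 3. Cytosolic ribosomal proteins turned to a median of 0.054 without tagmentation replicate 1 (adjusted p 0.795), in a range of -0.24 to 0.054 without each library in turn (adjusted p 2.75e-06 to 0.795), and the cause was not tested. Without the block, the call on LIF and BMP signalling also ended with no filter, a filter at a mean of 10 RPKM and quantile normalization, and that on ribosomal proteins with no filter; DNA replication and mitosis (median-ratio scaling, no filter), chromatin regulators (median-ratio scaling, without sonication replicate 3 or tagmentation replicate 2) and glycolysis (quantile normalization) gained one. With the block, DNA replication and mitosis (no filter) and glycolysis (quantile normalization) did. With the block, histones were called under each alternative except an estimated correlation. The others each lost their call with no filter and with fry. Ribosomal proteins also did without replicate 1 or 2 and with length correction, LIF and BMP signalling without replicate 3, and chromatin regulators without replicate 3 and with length correction, a filter at a mean of 10 RPKM and quantile normalization. For detected genes per library, tagmentation minus sonication was -358 and turned to 171 at 10 RPKM or more; without each library it was -723 to -44. The transcript length trend (0.11) was -0.083 to 0.24, and the GC content trend (-0.26) was -0.69 to 0.42, without each library. With pseudocount 0.1 they were 0.070 and -0.13, the latter higher in 2 of 3 pairs. With a filter at a mean of 10 RPKM they were 0.14, higher in 3 of 3 pairs, and -0.42, lower in 3 of 3 pairs. The ratio of spread between technical replicates (1.12) was 0.687 to 1.69 without each library, but by construction an SD over 2 libraries is lower in median than over 3. The share of the most abundant genes kept its direction under each alternative. Same-number pairs fixed that of the correlation. No permutation test here can reach 0.05. In the shallowest library 3 reads gave 0.0619 RPKM at the median length, and more for shorter genes.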

Other observations

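Except for the test of GC content on detected genes, the tests in this part were chosen after the results were seen. Developmental markers, like most genes, stood at different levels in the 3 replicate numbers, in both methods. T (brachyury), the T-box factor of early mesoderm, had 0.145 and 0.209 RPKM in the sonication and tagmentation libraries of number 1, 61.3 and 83.2 RPKM in number 2, and 7.08 and 12.6 RPKM in number 3. Lefty1, an inhibitor of Nodal signalling, had 40.0 and 26.2, 60.9 and 50.9, and 4.79 and 0.449 RPKM, and Cldn6, an epithelial tight junction gene, 73.8 and 59.1, 75.6 and 84.9, and 4.19 and 4.69 RPKM. Of the tested members, 5 of 5 mesoderm, 9 of 9 epiblast, 3 of 3 endoderm, 3 of 3 neuroectoderm, 3 of 5 trophoblast and 2 of 4 fibroblast markers differed between numbers (limma, adjusted p under 0.05), against 5577 of all 6327 genes (88.1%). Krt8 and Krt18, keratins of simple epithelia, were above 78 RPKM in each of the 6 libraries.

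Socs3, which is induced by LIF through Stat3, had 11.5 and 11.1 RPKM in number 1, 3.20 and 4.97 RPKM in number 2 and 0.351 and 0.466 RPKM in number 3, while Id3, a target of BMP signalling, had 46.4 and 28.5, 206 and 195, and 149 and 170 RPKM. Lin28a, an RNA-binding protein of stem cells, had 1.79 and 2.17, 4.09 and 6.82, and 9.33 and 29.2 RPKM. In the extreme, Hscb, Fkbp1b, Lysmd2 and Ptpla had 53.6 to 84.4 RPKM in both libraries of number 1 and were listed at 0 in the other 4.

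Genes thus differed between numbers although the labels describe 1 RNA source, and no biological difference between the numbers was tested because the design gives none. RNA from fibroblasts, as a contamination, was argued against, since Col1a1, Col1a2 and Col3a1, their most abundant collagen transcripts, reached at most 0.832 RPKM in any library. The fibroblast list, which holds Acta2, went the other way in number 1, with a summed 141 and 130 RPKM against 65.7 to 72.9 RPKM in the other numbers. GC content accounts for a small part: centring each library within 50 GC classes removed 11.1% of the sum of squares between numbers, and the mean correlation of number 1 with the others went from 0.506 to 0.543, still under 0.696 for numbers 2 and 3. A candidate explanation that stays open is chance sampling of few molecules before amplification, which would spare abundant genes: 0% of 38 genes above 1000 RPKM differed by 4-fold or more, against 63.4% of 5717 genes below 100 RPKM.

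The H2A histone genes were lower in tagmentation in 3 of 3 pairs, with a median of -1.21 (median SE 0.29). Short transcripts as the whole cause were tested against 200 single short genes of like level, of which 1 was as low. They were drawn from genes mostly longer than the H2A genes, so an effect of the shortest lengths stays open. Of 10000 lists matched on length member by member, 0 were as low, but H2A genes, as near-identical copies, do not count as separate members. High GC content was tested in the same way. After correction for the GC trend over all tested genes the median was still -0.82 (median SE 0.21), so this trend left much of the difference. Of 200 single GC-rich genes of like level, 0 were as low. They were drawn from genes mostly poorer in GC than the H2A genes, so an effect limited to the highest GC contents stays open. The 14 calls ended with the GC correction. The median t value of the 16 genes went from -4.19 to -3.86, and the degrees of freedom fell from 212 to 9.62. In the mixed counts, corrected t values at 212 called 9 of 16 genes, and uncorrected ones at 9.62 called 0. These counts do not separate the 2 changes, since both depend on the estimated spread. Reads shared between near-identical H2A genes may make 14 calls out of 1 change, since their profiles ran parallel with a median SD of 0.17, against a median of 1.17 in 10000 lists of like level, while what lowered the family as a whole stays open and no biological explanation was tested.

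Fewer genes reached 1 RPKM in tagmentation in 3 of 3 pairs. A lower depth was argued against, since in 2 of these pairs the tagmentation library had more alignments. Carryover between sonication libraries of different numbers was argued against too. A case was a gene at 50 RPKM or more in one number and under 0.05 RPKM in the tagmentation library of another. There were 64 cases, and a gene could count in more than 1. The median share found in the sonication library of that other number was 0% and the 90th percentile 0.117%, where 2% would be needed. GC content could contribute and stays open, since in the middle class of GC content the count was lower in 2 of 3 pairs (2, -49 and -83 genes), while the GC-poorest class changed by 69, -310 and -518 genes and the GC-richest by -93, -38 and -48 genes.

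Other splits of the 6 libraries were also tried. Without the block, the real split and the highest of the others gave 0 genes, so that 10 of 10 splits gave as many. With the replicate block, 1 of the 4 splits that part all 3 pairs gave as many genes, the real one with 208, and the highest of the others gave 0. In both cases the splits are too few for a share under 0.05.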
